A study of Rattus norvegicus with 18 samples.

How the data were processed

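RNA-seq of rat motor cortex was read for 18 libraries. At day 7 these were 3 inj and 3 Sham libraries from males, and at day 30 3 In and 3 S libraries of each sex. Per the labels, polyA RNA was extracted with the PureLink RNA Mini Kit and libraries were made by Novogene. Per the submitters' processing notes, reads were aligned with HISAT2 to rn6 and edgeR was used, and no version is given for either. The values deposited by the authors are raw counts of whole reads per gene symbol, in 1 table per day. The day 30 counts table as deposited ends with summary lines of reads that were ambiguous, not aligned or not uniquely aligned, so its counts come from uniquely aligned reads. It lists 31038 genes, 9706 of them with no read, and 27 names had been turned into dates. The day 7 table lists 12560 genes, each with reads in at least 3 libraries, and none encoded by mitochondria, so it was filtered before it was deposited, by a rule that is not given in the sources used here.

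Libraries were grouped by the day, sex and condition of their labels, and all columns were matched. Sham 1 and Sham 1-RNA carry the same number and would have been summed had they differed only by sampling noise. They were kept apart, but every pair of libraries within a group differed by more than that noise, so this does not show that they are different samples. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with default settings, robust quasi-likelihood F test) and Benjamini-Hochberg adjustment at a threshold of 0.05. The day 7 libraries were fitted together, with a common biological coefficient of variation of 0.175. The 12 day 30 libraries were fitted together (0.259), with a mean per group and contrasts for In minus S in each sex, for the difference of these effects and for female minus male in S and In. The 12397 genes in both tables were used for the difference of the male effects between days, fitted to the 12 male libraries (0.226). Gene lists were tested with camera of edgeR and limma 3.58.1 at a preset correlation of 0.01 between genes, with at least 5 tested members, and again with an estimated correlation. The 56 lists (17 of cell type markers, 37 of processes and 2 sex-linked ones used as label checks) and the comparisons were written before the data were examined. Overlaps of calls were tested with Fisher's exact test.

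Genes named in the text follow a rule set before the data were examined. Per comparison these are the 8 genes with the smallest adjusted p among those that rose and the 8 among those that fell (5 each for female against male), or, where none passed, the 3 with the smallest p in each direction. Up to 4 members of each list with a passing member or a passing test could be added, and Gfap, Aif1, Fos, App, Mapt, Tardbp, Sod1 and Apoe are fixed examples. Some genes that this rule names are not reported here. Mbp, Hba1, Fam183b's counts and the genes under other observations were chosen after their values were seen.

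CPM are counts scaled to a common library total, with TMM factors. Depth sets a floor: 3 counts correspond to between 1.09 and 1.23 CPM in the Sham libraries and to between 0.114 and 0.288 in the others. The test was checked on simulated data with 200 changed genes, of which it found 61.2% of the 2-fold changes at day 7 with 9 false calls. Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter at 1 CPM in 3 libraries, limma-voom with sample weights, leaving out each library, a replicate block, a fit to the compared groups alone, Sham 1 and Sham 1-RNA summed, and those added after the data were seen. The block joined day 30 libraries by number, within a sex for In against S and over all groups for female against male. A library alone in its number adds nothing to the contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Summary lines and lines without a gene name were dropped before the fit, a name listed again was kept as a separate gene, and levels were not compared between days.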

Results

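RNA was sequenced from rat motor cortex, described in the series as primary neurons enriched from this tissue, at day 7 and day 30 after spinal cord injury. The 18 libraries form 6 groups of 3: male inj and Sham at day 7, and In and S of each sex at day 30. The labels spell out inj and Sham but not In and S, so the day 30 names are kept as given. No source says that replicates are separate animals, so each p-value measures only the spread between these libraries. Nor does any source say whether Sham 1 and Sham 1-RNA are 1 sample, in which case Sham has 2 samples and not 3.

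The day 7 inj libraries held 14650528, 17013273 and 16974744 counts, and the Sham libraries 2895685, 2683105 and 3014083. At day 30 the totals ran from 14532252 in male In 1 to 18211986 in female S 3, apart from male S 1 with 27849794. RNA of cells other than neurons was present in both tables. Mbp, which encodes a major protein of myelin, took 11.3 ± 4.8% of the counts in Sham and 5.65 ± 1.02% in inj (SD, n = 3), but Sham 1-RNA, with 5.81% (95% Wilson interval 5.78 to 5.83), lay within the inj range (4.94 to 6.83%) and apart from Sham 1 (14.5%) and Sham 3 (13.6%). The day 30 libraries held between 2.12% (female S 2, interval 2.11 to 2.12) and 3.84% (male In 3, 3.83 to 3.85), except male In 1 with 0.551% (0.547 to 0.555). Mitochondrially encoded genes are absent from the day 7 table and took more of the day 30 counts in males than in females. The Mbp shares are therefore not comparable between days or sexes. The sex labels held at day 30. Eif2s3y, a Y-linked gene for a translation initiation factor, had 1349 counts over the male S libraries and 0 over the female S libraries. Over the In libraries it had 1178 in males and 3 in females.

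The day 7 comparison asks how the male motor cortex differed a week after injury from Sham. Genes of blood vessels and of microglia were several-fold higher in the inj libraries, and some genes of inhibitory neurons were lower. All 12 tested endothelial markers rose, with a median log2 fold change of 2.82, as did all 12 markers of pericytes and smooth muscle, with a median of 2.61. Cldn5, a tight junction protein of brain endothelium, rose by 3.32 ± 0.17 (log2 fold change ± SE, n = 3 per group), from 63.4 ± 2.75 to 635 ± 89.4 CPM (mean ± SD). Of the microglia and macrophage markers, 17 of 19 rose, with a median of 2.10, while 9 of 14 inhibitory neuron markers fell and 2 rose, with a median of -0.91. None of these 4 lists held with an estimated correlation (adjusted p = 0.12 for endothelial, 0.0637 for pericyte, 0.0637 for microglia and 0.416 for inhibitory neuron markers), and the inhibitory call also ended without Sham 1-RNA (adjusted p = 0.0561, range over the alternatives with the preset correlation 0.00457 to 0.0561).

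Among vascular genes, Flt1, a receptor for vascular growth factors, rose by 2.92 ± 0.17, and Pecam1, an endothelial adhesion molecule, by 3.19 ± 0.22. Itm2a, listed with the endothelial markers, rose by 3.16 ± 0.20, Bcam, a laminin-binding adhesion molecule, by 3.14 ± 0.15, and Flna, an actin cross-linker, by 3.20 ± 0.17. Sema3g, a semaphorin, rose by 3.44 ± 0.23 and Crispld2 by 3.48 ± 0.23. Notch3, a receptor of mural cells, rose by 3.03 ± 0.26, the growth factor receptor gene Pdgfrb by 2.51 ± 0.17 and smooth muscle actin, Acta2, by 3.31 ± 0.30. Collagen and basement membrane genes rose in 10 of 14 tested members, or 11 when adjusted over the list alone (adjusted p = 0.352 with an estimated correlation), among them Col4a1 (2.29) and Fn1, which encodes fibronectin (2.29). Slc2a1, the glucose transporter of the blood-brain barrier, rose by 2.89 ± 0.21.

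Of the complement and antigen presentation genes, 25 of 30 rose, or 27 adjusted over the list alone, with a median of 1.68 (adjusted p = 0.12 with an estimated correlation). These included C1qa and C1qb, which encode chains of complement C1q (2.48 and 2.61), Cd74, the invariant chain of antigen presentation (1.85), and RT1-A1, a class I histocompatibility gene (2.08). Csf1r, the receptor that keeps microglia alive, rose by 2.74 ± 0.19, and Ctss, a lysosomal protease, by 2.33 ± 0.17. Aif1, another microglial marker, stood at -0.27 ± 0.15 and did not pass the test (adjusted p = 0.192), although it did by limma-voom (0.0435, range 0.0435 to 0.968). Disease-associated microglia genes rose in 12 of 16 members and fell in 1 (Trem2, a microglial receptor, 2.32), autophagy and lysosome genes rose in 16 of 32 and fell in 1 (Ctsz, a cathepsin, 2.32), and cytokine and NF-kappaB genes rose in 12 of 18 and fell in 1 (Tlr2, an innate immune receptor, 2.25), with adjusted p = 0.352, 0.12 and 0.384 in that order with an estimated correlation. Interferon response genes rose in 8 of 24 members (Irf1, a transcription factor, 1.45), a call that ended without inj 4 (adjusted p = 0.0812) or Sham 1-RNA (0.125, range 0.00469 to 0.125), and also with an estimated correlation (0.844).

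Inhibitory neuron genes that fell included Gad1, which makes GABA (-1.17 ± 0.18), and the neuropeptide genes Vip (-1.67) and Npy (-2.06), whereas Cck, another neuropeptide gene, rose by 0.96 ± 0.16. Striatal neurons also make GABA, and of their markers 5 of 11 fell and 1 rose, with a median of -0.46, though that list did not pass (adjusted p = 0.277). Pan-neuronal markers were divided, with 3 of 14 falling, such as the neurofilament gene Nefm (-1.36), and 1 rising (Thy1, 0.70), for a median of -0.04 that became 0.24 with library totals as scale. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, rose by 1.06 ± 0.21. Excitatory neuron markers as a list went both ways, with a median of 0.03 (quartiles -0.24 to 0.46). Layer 5 and corticospinal neuron markers had a median of -0.28 (quartiles -0.70 to 0.08), and neither list passed. Reactive astrocyte genes rose in 9 of 17 members and fell in 2 (adjusted p = 0.844 with an estimated correlation), among them Vim, an intermediate filament gene, which rose by 1.24 ± 0.15. Gfap, the filament gene that marks astrocytes, fell by 1.98 ± 0.23, while the astrocyte markers as a list went both ways (median 0.08, mean -0.12, lower by camera with adjusted p = 0.575). Oligodendrocyte markers did not move with the vascular genes: 4 of 15 fell, such as the cytoskeletal gene Ermn (-1.49), and 1 rose, with a median of -0.14 that turned to 0.18 with library totals as scale. Oligodendrocyte precursor markers rose in 5 of 10 members (Pdgfra, a growth factor receptor, 1.74), a call that ended without Sham 1-RNA (adjusted p = 0.0637, range 0.000701 to 0.0637), and also with an estimated correlation (0.525).

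**Figure D1:**
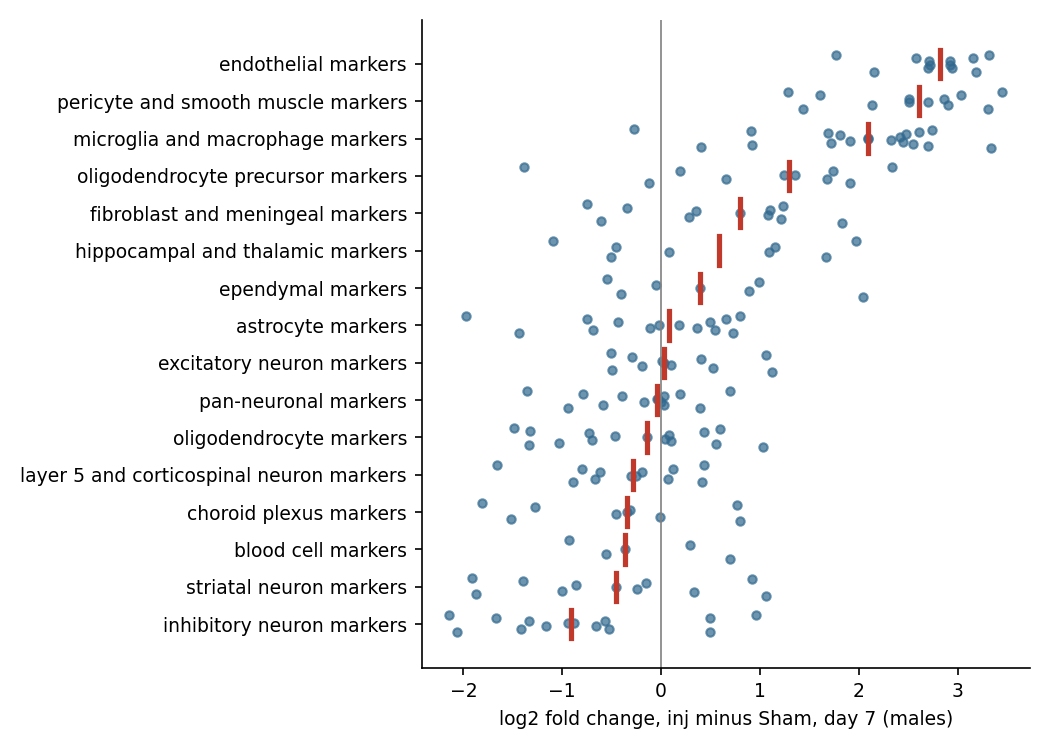
Log2 fold changes (inj minus Sham at day 7, horizontal axis) of the tested members of each cell type list, 1 point per gene, with the median as a bar. Endothelial markers had a median of 2.82 and oligodendrocyte markers of -0.14, the latter above 0 with library totals as scale.

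Immediate early genes rose in 9 of 20 members, or 10 adjusted over the list alone (adjusted p = 0.844 with an estimated correlation), including Fos (1.49 ± 0.26), Junb (1.58), Ier2 (1.89) and Dusp1, a phosphatase that ends kinase signalling (2.06). Endoplasmic reticulum stress genes rose in 12 of 24 and fell in 1 (Herpud1, a degradation factor of that compartment, 2.35), and perineuronal net and matrix genes rose in 9 of 18 (Timp3, a metalloproteinase inhibitor, 2.13), with adjusted p = 0.666 and 0.352 with an estimated correlation. Alzheimer disease genes rose in 12 of 30 and fell in 2 (adjusted p = 0.705 with an estimated correlation). Those that rose included the microglial genes Trem2 and Inpp5d (1.19) and Grn, which encodes progranulin (2.33). App stood at 0.29 ± 0.19 without passing the test (adjusted p = 0.283), although it passed with library totals as scale (0.58, 0.0232, range 0.0232 to 0.566), and Mapt, which encodes tau, fell (-0.86). Apoe, a lipid carrier, rose by 0.81 ± 0.22. The Apoe call ended without inj 2 (adjusted p = 0.0862), inj 4 (0.0748), Sham 1 (0.0717) or Sham 3 (0.057), with a range of 0.000742 to 0.0862 over all alternatives. The Mapt call ended without inj 2 (0.0576), Sham 1 (0.0525) or Sham 3 (0.0552), with a range of 3.85e-05 to 0.0576. Of the genes linked to amyotrophic lateral sclerosis, 2 of 25 rose (Kif5a, an axonal motor protein, 1.27) and 4 fell, and the list did not pass its test (adjusted p = 0.375). Tardbp (-0.23 ± 0.13, adjusted p = 0.198) and Sod1 (-0.09 ± 0.14, 0.631) did not pass. Of the Parkinson disease genes, 3 rose and 3 fell out of 18 (list adjusted p = 0.931).

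The genes with the smallest adjusted p among those that fell were Cntnap5b, of a family of neuronal adhesion molecules (-5.91 ± 0.25, from 150.3 to 2.49 CPM), Srrm4, a splicing regulator of neurons (-3.82 ± 0.20), Knop1 (-3.67 ± 0.20), the splicing factor gene Rbm39 (-3.55 ± 0.19), Srek1ip1 (-2.59 ± 0.14), the Wnt agonist gene Rspo3 (-3.13 ± 0.18), Hsp90aa1, a chaperone (-2.92 ± 0.17), and the chromatin gene Arid4b (-3.13 ± 0.19). Ribosomal protein genes were lower in 71 of 76 members with a median of -0.33, or -0.0209 with library totals as scale. Of these, 10 passed the test over all genes and 0 adjusted over the list alone, and the list's call ended without Sham 1 (adjusted p = 0.133, range 4.54e-09 to 0.133) and with an estimated correlation (0.956).

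In all, 2276 of 11786 genes rose and 1814 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With library totals as scale the median of all genes lay at 0.28 on the log2 scale and the calls divided into 3365 that rose and 957 that fell. Of the 52 lists tested, 17 passed with the preset correlation and 0 with an estimated one. The Sham libraries, with lower totals than the inj libraries in each case, included Sham 1 and Sham 1-RNA, which differed by more than sampling noise (chi-square per gene 32.2), as did Sham 1 and Sham 3 (3.3). With Sham 1 and Sham 1-RNA summed 4484 genes differed.

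**Figure D2:**
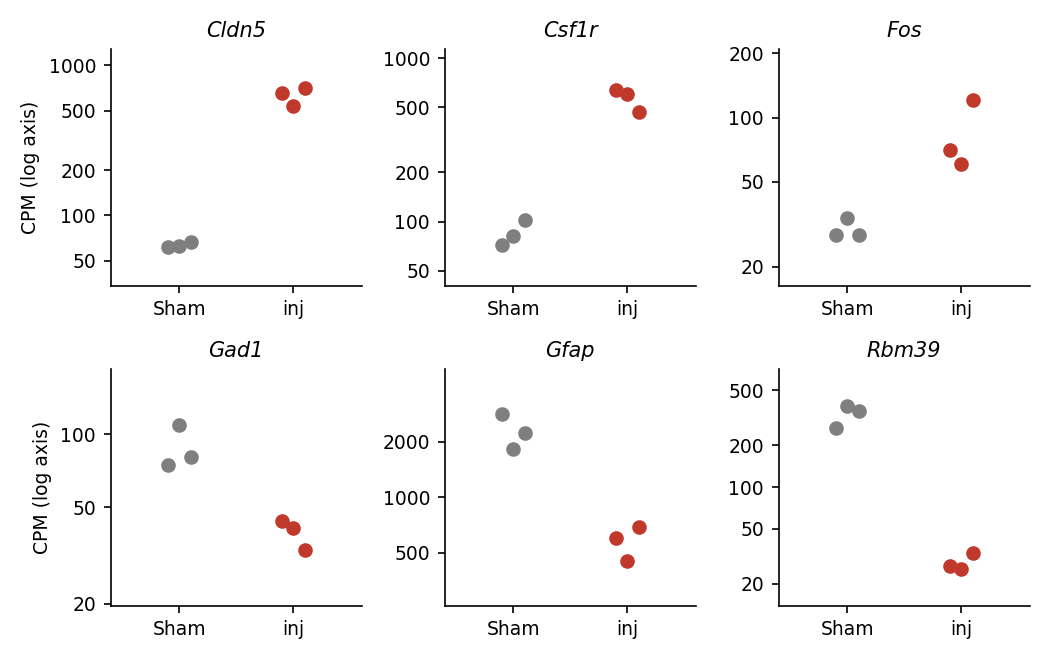
CPM (log axis) of 6 genes in each day 7 library, 1 point per library. Cldn5 lay near 635 in inj and 63.4 in Sham on average, and Rbm39 at 28.7 and 337.

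At day 30 the same question was asked within males, comparing In with S. The gene lists that passed with a preset correlation between genes, none of which did with an estimated one (adjusted p = 0.738 to 0.826), had medians between -0.47 and 0.51 (log2 fold change). Subunits of respiratory chain complexes II to V were higher in In in 36 of 36 members, with a median of 0.31, and complex I subunits in 32 of 33, with a median of 0.27. Metabotropic glutamate receptor and postsynaptic scaffold genes were lower in 21 of 25 members (median -0.47), and voltage-gated ion channel genes in 32 of 37 (median -0.25). Microglia and macrophage markers were higher in all 19 members (median 0.36), and complement and antigen presentation genes in 27 of 29 (median 0.44). Among other cell types, all 11 fibroblast and meningeal markers (median 0.51) and 12 of 14 astrocyte markers (0.44) were higher, while 14 of 15 oligodendrocyte markers (-0.32) and 10 of 13 pan-neuronal markers (-0.19) were lower. Medians of excitatory neuron markers (-0.51), blood cell markers (1.84) and choroid plexus markers (0.71) lay as far from 0 or further without passing (adjusted p = 0.0576, 0.151 and 0.389). No single gene passed the test.

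The genes with the smallest p were, higher in In, Tead2, a transcription factor of the Hippo pathway (2.03 ± 0.42, n = 3 per group), Ifitm2, an interferon-induced membrane protein (0.91 ± 0.21), and the alkaline phosphatase gene Alpl (0.86 ± 0.22). Lower were Arnt, a partner of hypoxia-inducible factors (-1.38 ± 0.29), the chromatin remodelling gene Ino80e (-1.06 ± 0.23) and the neuronal adhesion gene Cntn5 (-1.33 ± 0.31). Each had an adjusted p of 0.599 by edgeR, while DESeq2 called Tead2 (0.0148, range over the alternatives 0.0148 to 1) and edgeR without male In 1 and male S 2 called Ino80e (0.0319, range 0.0319 to 0.976). Among disease genes, App stood at -0.10 ± 0.22, Mapt at -0.55 ± 0.21, Tardbp at 0.11 ± 0.15, Sod1 at 0.55 ± 0.19 and Apoe at 0.87 ± 0.31, none past the threshold. Gfap (-0.01 ± 0.23), Aif1 (0.64 ± 0.32) and Fos (-0.11 ± 0.38) did not pass either.

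By edgeR's test 0 of 15074 genes passed, with 1232 at an unadjusted p under 0.05 where chance gives 754. That excess depended on the libraries and the fit. The number was 638 of 13665 when only these groups were fitted and 707 without male In 1 or without male S 2. It was 465 of 15390 without both, but 1843 without male S 1 and 1877 with a replicate block. Male In 3 and male S 4 are each alone in their number within males and add nothing with the block. The result with the block thus rests on male In 1, male In 2, male S 1 and male S 2. DESeq2 called 2 and limma-voom 0, and edgeR called 1 without male In 1 and 1 without male In 2. In simulated data of this size the test recovered 38.8% of 2-fold and 71.2% of 4-fold changes. The lists were tested with camera at a preset correlation, and 17 of 54 passed. With an estimated correlation 0 passed, and adjusted p = 0.738 for the respiratory chain, glutamate receptor, ion channel, microglia, complement and fibroblast lists and 0.753 for the astrocyte, oligodendrocyte and pan-neuronal lists. Part of these calls rested on male In 1, the library with the low share of Mbp and the higher counts of the haemoglobin gene Hba1 (304 CPM): without it 8 lists passed, the complex I call ended (adjusted p = 0.108, range over the alternatives 1.64e-09 to 0.3), and so did those of complement (0.519, range 7e-07 to 0.972), fibroblast (0.239, range 3.58e-05 to 0.296), oligodendrocyte (then higher, 0.802, range 6.46e-11 to 0.802), pan-neuronal (0.232, range 0.00135 to 0.232) and astrocyte genes (0.0527, range 1.99e-06 to 0.3). The pan-neuronal and astrocyte calls also ended without male S 1 (0.0829 and 0.233). Without male In 1 and male S 2 together the calls of complexes II to V (0.296, range 1.64e-09 to 0.296) and of microglia (0.268, range 2.9e-07 to 0.268) ended as well, and the oligodendrocyte and complement lists changed direction (0.6 and 0.972).

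In females at day 30, the lists of markers of the choroid plexus, the tissue that secretes cerebrospinal fluid, and of ciliated ependyma were higher in In than in S. All 9 tested choroid plexus markers were higher in In, with a median log2 fold change of 6.05. Of these, 1 passed over all genes and 9 when adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.0135). Ependymal markers were higher in 7 of 9 members, with a median of 1.29 (adjusted p = 0.0136 with an estimated correlation), and 1 passed over all genes.

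Only 5 genes passed the test, and all rose. Foxj1, the master regulator of motile cilia, rose by 3.21 ± 0.50 (n = 3 per group, adjusted p = 0.0359), from 0.619 ± 0.204 to 5.79 ± 2.26 CPM (mean ± SD). Plvap, a protein of fenestrated vessels, rose by 3.60 ± 0.55 (adjusted p = 0.0358), from 0.803 ± 0.0993 to 9.8 ± 6.89. Folr1, a folate receptor of choroid plexus epithelium, had 1111 counts over the In libraries and 3 over the S libraries, a ratio of 367 after scaling (95% counting interval 125 to 1781, adjusted p = 0.0358). Tmem72 had 529 and 1 (ratio 524, interval 93.6 to 20730.2, adjusted p = 0.0358), and the organic anion transporter gene Slco1a5 591 and 3 (ratio 195, interval 66.4 to 949, adjusted p = 0.0447). Intervals cover counting error only, and the In libraries differed among themselves: Folr1 had 60, 262 and 789 counts in In 1, In 2 and In 3.

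Interferon response genes were higher in 21 of 23 members (median 0.30) and immediate early genes in 17 of 20 (median 0.30), with adjusted p = 0.259 and 0.249 with an estimated correlation. Glucocorticoid response genes were higher in 14 of 18 (median 0.23, adjusted p = 0.749 with an estimated correlation), a call that ended without In 1 (0.762) or S 1 (0.25, range over the alternatives 1.3e-07 to 0.762). Microglia markers (median -0.10), astrocyte markers (-0.18) and pan-neuronal markers (median -0.01 but mean 0.01, and a median of 0.05 with library totals as scale) did not pass. Gfap (0.02 ± 0.23), Aif1 (-0.22 ± 0.31), Fos (0.28 ± 0.39), App (0.01 ± 0.22), Mapt (0.04 ± 0.21), Tardbp (-0.03 ± 0.14), Sod1 (0.15 ± 0.19) and Apoe (-0.12 ± 0.31) each had an adjusted p of 1.

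**Figure D3:**
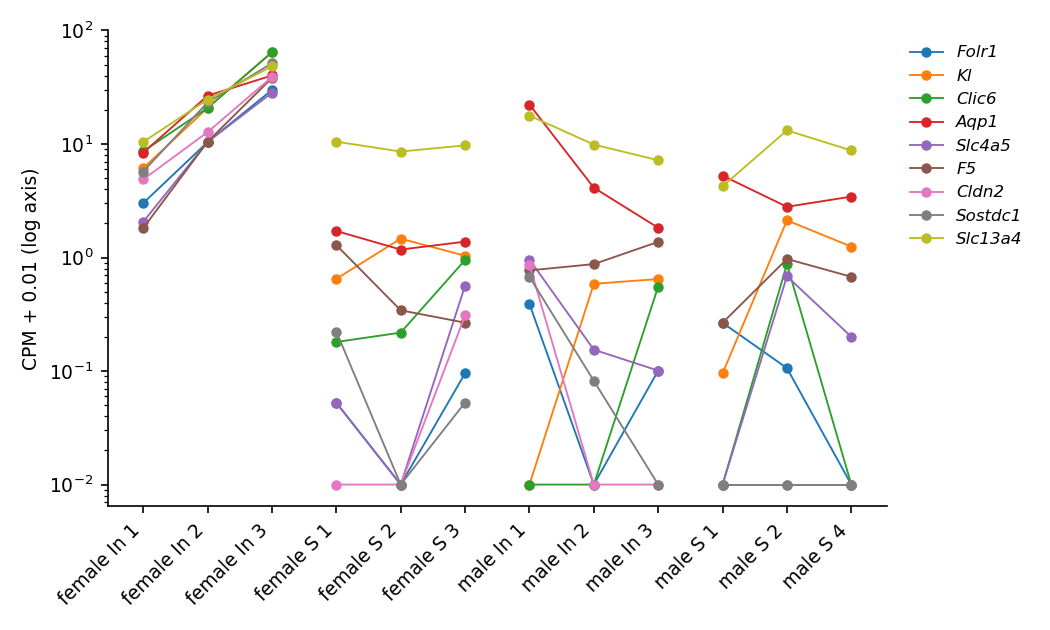
CPM of the 9 choroid plexus markers (log axis, with 0.01 added so that 0 can be drawn) in each day 30 library, 1 line per gene. The female In libraries lay above the others for Folr1, Kl, Clic6, Slc4a5, F5, Cldn2 and Sostdc1, with the highest values in In 3.

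By edgeR 261 of 15074 genes had an unadjusted p under 0.05, fewer than the 754 that chance gives. When only the female libraries were fitted there were 446 of 14703. The count of 5 genes depended on single libraries: it was 24 without In 1, and 0 without In 2, without In 3, without S 1, without S 2 or without S 3. DESeq2 called 33, limma-voom 0, and edgeR fitted to the female libraries alone 0. Of the 5 genes, Folr1 also lost its call with no filter (adjusted p = 0.12, range over all alternatives 2.55e-05 to 1), Plvap with a replicate block (0.0858, range 4.23e-07 to 1) and Slco1a5 with library totals as scale (0.069, range 4.23e-07 to 1).

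The title of the series asks whether the response depended on sex, and this was tested as the female In minus S difference less the male one. The lists below passed with a preset correlation and 0 did with an estimated one (adjusted p = 0.571 or 0.726). Choroid plexus markers were again the list with the largest difference, higher in all 9 members with a median of 3.95. Respiratory chain genes had a lower effect in females than in males, in 35 of 36 subunits of complexes II to V (median -0.32) and 31 of 33 of complex I (median -0.33). Within females the In minus S medians of these lists were -0.03 and -0.01, against 0.31 and 0.27 within males. The female effect was also lower for 18 of 19 microglia and macrophage markers (median -0.47), 12 of 14 astrocyte markers (-0.64) and all 5 blood cell markers (-2.87). Ependymal (7 of 9, median 1.15), excitatory neuron (8 of 11, 0.61) and oligodendrocyte markers (14 of 15, 0.45) were higher. Immediate early genes were higher in 16 of 20 members (median 0.40). Single genes with the smallest p were Foxj1 (3.08 ± 0.69), Plvap (3.46 ± 0.79) and Fam183b, which had 24, 32 and 40 counts in female In and 0 in each male In library, against 0, 4 and 1 in female S and 11, 3 and 3 in male S, and on the other side Tead2 (-2.50 ± 0.56), Gpr84, a receptor of activated microglia (-0.94 ± 0.25), and Ifitm2 (-1.09 ± 0.30).

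Among the disease genes App stood at 0.11 ± 0.31, Mapt at 0.59 ± 0.30, Tardbp at -0.14 ± 0.20, Sod1 at -0.40 ± 0.27 and Apoe at -0.99 ± 0.44, and among glial and activity genes Gfap at 0.02 ± 0.33, Aif1 at -0.86 ± 0.45 and Fos at 0.38 ± 0.55. The adjusted p of these genes ran from 0.94 to 0.993.

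None of the genes with the smallest p passed by edgeR (adjusted p = 0.94 for each), while DESeq2 called Foxj1 (0.0405, range over the alternatives 0.0405 to 1), Plvap (0.0405, range 0.0405 to 1) and Tead2 (0.0387, range 0.0387 to 1). By edgeR 0 of 15074 genes were called, with 619 at an unadjusted p under 0.05 where chance gives 754, 6 by DESeq2 and 0 by limma-voom. In simulated data the test recovered 2.99% of 2-fold and 54.5% of 4-fold changes. Of 54 lists 17 passed with the preset correlation and 0 with an estimated one, where adjusted p = 0.571 for choroid plexus, ependymal and immediate early genes and 0.726 for the other lists named above. The list count was 11 without female In 2, without male In 1 or without male S 1, and the complex I call ended without male In 1 (adjusted p = 0.062, range over the alternatives 3.49e-08 to 0.178), as did the oligodendrocyte call (0.468, range 1.41e-11 to 0.73). The ependymal call ended without male In 2 (0.0652) or male S 1 (0.0605), with a range of 5.02e-06 to 0.0652. The astrocyte call ended without female In 2 (0.0668), female S 3 (0.149) or male S 1 (0.0615), with a range of 2.94e-10 to 0.149. The blood cell call ended without female In 2 (0.133), female S 1 (0.0853), female S 3 (0.142), male In 1 (0.294), male S 1 (0.0585) or male S 4 (0.0926), with a range of 6.41e-08 to 0.314. For excitatory neurons it ended without female In 2 (0.276), female In 3 (0.0636), female S 1 (0.0853), female S 3 (0.202), male In 1 (0.38), male S 1 (0.174) or male S 2 (0.0858), with a range of 0.00468 to 0.515. Without male In 1 and male S 2 together the call of complexes II to V ended too (0.178, range 9.14e-09 to 0.178). Across genes, which are not independent replicates, the male and female fold changes had a Pearson correlation of 0.0152 and a Spearman correlation of -0.0282.

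Female and male S libraries were compared to describe the background of sex at day 30. After TMM scaling, mitochondrially encoded and ribosomal protein genes were lower in females, and vascular genes were higher. Mitochondrially encoded genes took 32.2 ± 0.969% of the counts in female S and 57.5 ± 3.11% in male S (SD, n = 3), and 10 of 13 tested members fell (median -1.73). Ribosomal protein genes fell in 49 of 73 members, or 66 adjusted over the list alone (median -0.90). Endothelial markers rose in 6 of 13 (9 adjusted over the list alone, median 0.59) and pericyte and smooth muscle markers in 4 of 11 (7, median 0.65). No list here or below held with an estimated correlation, where adjusted p = 0.365 for ribosomal, 0.171 for mitochondrially encoded and endoplasmic reticulum stress, 0.207 for endothelial, 0.485 for pericyte, 0.522 for complexes II to V and collagen, 0.549 for complex I and 0.71 for microglia genes.

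Named by the smallest adjusted p, Slco2b1, an organic anion transporter, rose by 1.89 ± 0.14 (female minus male, n = 3 per group), Rgs5, a pericyte gene, by 1.94 ± 0.20, Cd93 by 1.76 ± 0.18 and Cdh5, the cadherin of endothelial junctions, by 1.57 ± 0.17. Cx3cr1, the fractalkine receptor of microglia, rose by 1.98 ± 0.19, and microglia and macrophage markers rose in 3 of 19. Eif2s3y and Kdm5d, both Y-linked, were at least 719-fold and 216-fold lower in females against a floor of 3 counts over the group, and Ddx3, the Y-linked helicase, had a ratio of 589 (counting interval 201 to 2858). The respiratory chain genes ND4 and ND5 of the mitochondrial genome fell (-2.12 ± 0.25 and -2.09 ± 0.29), the ND5 call ending with a replicate block (adjusted p = 0.0512, range over all alternatives 1.26e-12 to 0.0512). Endoplasmic reticulum stress genes rose in 4 of 24, and collagen and basement membrane genes in 4 of 20 (Fn1, 1.08, a call that ended with the block, 0.0585, range 1.52e-07 to 0.0585). Gfap fell by 1.28 ± 0.24 (adjusted p = 0.0117), a call that ended without female S 1 (0.0934) or male S 4 (0.064), with the block (0.136) and with library totals as scale (-0.42, 0.1), with a range of 2.51e-05 to 0.136. Ccl3, a chemokine of microglia, fell by 3.32 ± 0.52. Fos (-1.43 ± 0.39, adjusted p = 0.0711), Mapt (-0.71 ± 0.21, 0.081), App (0.45 ± 0.22, 0.287), Aif1 (-0.32 ± 0.31, 0.635), Sod1 (-0.13 ± 0.19, 0.779), Apoe (0.10 ± 0.31, 0.904) and Tardbp (0.04 ± 0.14, 0.919) did not pass, although Mapt did without male S 1 (0.0387), by DESeq2 (0.0179), by limma-voom (0.0228), with no filter (0.047) and with only these groups (0.0234, range 0.0179 to 0.435), and Fos by DESeq2 (0.00416) and with only these groups (0.024, range 0.00416 to 0.204). With library totals as scale App (1.30), Apoe (0.95), Tardbp (0.90) and Sod1 (0.71) passed as higher. Nuclear-encoded respiratory chain subunits were lower, with 2 of 36 of complexes II to V (16 adjusted over the list alone, median -0.40) and 2 of 33 of complex I (7, median -0.36) falling.

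In the S libraries 256 of 15074 genes rose in females and 191 fell (edgeR). With library totals as scale the median of all genes was 0.88, 8964 genes rose and 34 fell. The medians of ribosomal protein genes and of mitochondrially encoded genes then shrank to -0.04 and -0.85, and the nuclear respiratory chain medians turned to 0.46 and 0.49, so each change here is relative to the other genes. The count was 66 without female S 1, 116 without female S 2, 162 without female S 3, 159 without male S 2 and 68 without male S 4, against 1038 by DESeq2 and 21 with a replicate block. That block joins libraries of both sexes, and of In and S, by number alone, a pairing that no source gives. Male S 4 is the only library with its number, so with the block it adds nothing to this comparison. The male side of the results with the block thus rests on male S 1 and male S 2. Deviations from the group means correlated at 0.0401 for number 1 and -0.0123 for number 2. For female S 3 and male S 4 the correlation was 0.0718. Male S 4 stood apart in quality, with 40.6% of its reads not uniquely aligned and 48.0% assigned to genes, against 16.4 to 25.6% and 62.3 to 71.0% in the other day 30 libraries.

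**Figure D4:**
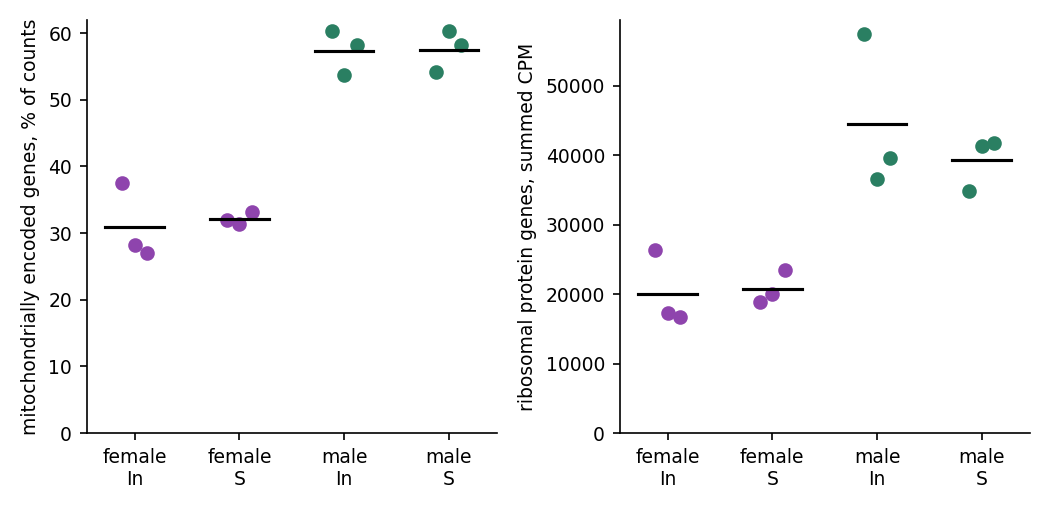
Percent of counts in mitochondrially encoded genes (left) and summed CPM of ribosomal protein genes (right) in each day 30 library, 1 point per library, with the group mean as a bar. The female libraries lay at or below 37.5% and the male libraries at or above 53.7%.

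Between the In libraries, after TMM scaling, ribosomal, mitochondrially encoded and nuclear respiratory chain genes were again lower in females, and endothelial genes higher. Ribosomal protein genes fell in 68 of 73 members (median -1.12), mitochondrially encoded genes in 11 of 13 (median -1.72), subunits of complexes II to V in 26 of 36 (median -0.78) and of complex I in 23 of 33 (median -0.67). Voltage-gated ion channel genes rose in 9 of 37 members (14 adjusted over the list alone, median 0.69), endothelial markers in 7 of 13 (median 0.50) and choroid plexus markers in 7 of 9 (median 6.14). Oxidative stress response genes fell in 9 of 25 members (median -0.50). No list here or below held with an estimated correlation, where adjusted p = 0.299 for the ribosomal, mitochondrially encoded, complexes II to V, endothelial, oxidative stress and axon growth inhibitor lists, 0.358 for complex I, 0.374 for choroid plexus, 0.63 for ion channels and 0.823 for astrocytes.

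Examples were Rplp1, a protein of the large ribosomal subunit (-1.81 ± 0.22, n = 3 per group), Atp5l, of the ATP synthase (-1.13 ± 0.18), Ndufb9, of complex I (-1.07 ± 0.18), and ND4 (-2.03 ± 0.25), all of which fell. With library totals as scale the calls of Atp5l (-0.22) and Ndufb9 (-0.18) ended. Cdh5 (1.75 ± 0.18), Slco2b1 (1.76 ± 0.15), Rgs5 (1.76 ± 0.20), Cd93 (1.57 ± 0.18) and Tgfbr2, a receptor for transforming growth factor beta (1.18 ± 0.14), rose. Among ion channels, Kcna2, a potassium channel of axons, rose (0.95), a call that ended without female In 2 (adjusted p = 0.0865) or In 3 (0.0648) and with only these groups (0.0607, range over all alternatives 9.57e-05 to 0.0865). Axon growth inhibitor receptors and ligands rose in 6 of 23 members (Plxna2, a semaphorin receptor, 2.02 ± 0.25). Gpx4, a lipid peroxide reductase (-1.17), and Txn1, which encodes thioredoxin (-1.15), fell. Astrocyte markers fell in 3 of 14, including Gfap (-1.26 ± 0.24), with a median of -0.38. With library totals as scale the calls of Gpx4 (-0.26), Txn1 (-0.25) and Gfap (-0.39) ended. Aif1 fell (-1.18 ± 0.32, adjusted p = 0.0288), a call that ended without female In 2 (0.113), female In 3 (0.104) or male In 1 (0.0694), with no filter (0.0787), with only these groups (0.0758) and with library totals as scale (-0.29, 0.441), with a range of 0.00215 to 0.441. Of the other fixed examples, Apoe (-0.88 ± 0.31, 0.0769), Sod1 (-0.53 ± 0.19, 0.0779), Fos (-1.05 ± 0.39, 0.097), App (0.57 ± 0.22, 0.105), Tardbp (-0.10 ± 0.14, 0.699) and Mapt (-0.12 ± 0.21, 0.757) did not pass. By DESeq2 Apoe (0.0255, range 0.0255 to 0.935), Sod1 (0.0483, range 0.0483 to 0.295) and Fos (0.0296, range 0.0283 to 0.749) did, Fos also with a replicate block (0.0283), and with library totals as scale App (1.48), Tardbp (0.79) and Mapt (0.79) passed as higher. Ddx3 was at least 666-fold lower in females against 3 counts over the group, and Eif2s3y and Kdm5d had ratios of 794 (counting interval 271 to 3857) and 235 (79.9 to 1147).

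Between the In libraries 920 genes rose in females and 993 fell (edgeR, 15074 tested). The count was 578 without female In 2, 821 without female In 3 and 668 when only these libraries were fitted. With library totals as scale the median of all genes was 0.94 (8916 rose, 53 fell), the medians of ribosomal and mitochondrially encoded genes shrank to -0.24 and -0.85, and those of complexes II to V, complex I, oxidative stress and astrocyte genes turned to 0.13, 0.24, 0.40 and 0.55. The S and In comparisons, which share no libraries, had 182 genes that rose in both (15.6 by chance, Fisher's exact p = 1.17e-165) and 163 that fell in both (12.6 by chance, p = 3.19e-166), genes not being independent. Both came from a shared fit, and a batch that followed sex would enter both. The overlap therefore does not tell sex from batch.

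The last comparison asks whether the male difference at day 30 differed from that at day 7, as the day 30 In minus S effect less the day 7 inj minus Sham effect. The vascular and microglial genes that were higher a week after injury were not higher to the same degree at day 30. All 12 endothelial markers fell in this contrast (median -2.76), with 9 of 12 pericyte and smooth muscle markers (median -2.29) and 11 of 19 microglia and macrophage markers (median -1.64). Inhibitory neuron markers moved the other way, with 5 of 15 rising and 1 falling (median 1.20). Of 53 lists 21 passed with the preset correlation and 1 with an estimated one, the endothelial list (adjusted p = 0.0123), while adjusted p = 0.056 for pericytes, 0.172 for microglia and 0.27 for inhibitory neurons.

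The endothelial genes Cldn5 (-3.01 ± 0.21, log2 ± SE, n = 3 per group), Pecam1 (-3.16 ± 0.27), Flt1 (-2.88 ± 0.27), Itm2a (-2.85 ± 0.28) and the receptor gene Tie1 (-2.61 ± 0.25) fell, as did Bcam (-2.94 ± 0.21), Slc7a5, an amino acid transporter of the blood-brain barrier (-3.08 ± 0.25), and Podxl, a sialomucin of vessel lumens (7.99-fold lower). Csf1r (-2.32), Tmem119, a marker of microglia (-3.20), and C1qa (-1.98) fell too. Gad1 (1.34), Sst (1.63) and Vip (2.79) rose, as did Gfap (2.02 ± 0.28). With the smallest adjusted p among those that rose were Cntnap5b (6.02 ± 0.40), the splicing factor genes Srek1 (5.22 ± 0.43), Srsf11 (4.67 ± 0.38), Luc7l3 (4.86 ± 0.44) and Rbm25 (4.26 ± 0.41), the dynein gene Dync1i2 (2.97 ± 0.26), Fam133b (3.02 ± 0.28) and Taf1d (5.88 ± 0.56). Fos fell (-1.54 ± 0.47, adjusted p = 0.0462), a call that held without In 1, S 4 or inj 3 and ended without any other single library, with Sham 1 and Sham 1-RNA summed and with inj thinned, with a range of 0.00607 to 0.108 over all alternatives. App (-0.33 ± 0.35, adjusted p = 0.588), Mapt (0.37 ± 0.35, 0.54), Sod1 (0.70 ± 0.25, 0.0828), Aif1 (0.96 ± 0.42, 0.155), Tardbp (0.39 ± 0.18, 0.18) and Apoe (0.11 ± 0.38, 0.895) did not pass, although Sod1 (0.0295, range 0.0295 to 0.485) and Tardbp (0.0434, range 0.0434 to 0.959) did by limma-voom.

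Of 11693 genes 616 rose and 902 fell (edgeR), or 258 and 1577 with library totals as scale, where the median of all genes was -0.28. Without inj 2 the count was 1004. Leaving out 1 library, the number that rose ran from 327 (Sham 1) to 939 (male In 1). The number that fell ran from 655 (inj 2) to 1089 (male In 1). Of the genes that rose at day 7, 60.9% were also higher in male In at day 30, and of those that fell 66.0% were lower, none of them past the threshold there. The same share over all genes was not computed. Across the 11132 genes tested on both days the fold changes had a Pearson correlation of 0.118 and a Spearman correlation of 0.158.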

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

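The tests by thinning, by comparing cell types, by comparing endothelial with ribosomal genes, by leaving out mitochondrially encoded genes, by leaving out In 3 and by the mitochondrial share of each sex were chosen only after the result was seen. The tests by the nuclear-retained list, by the second choroid plexus list and by other splits of the libraries were set before. For the nuclear-retained list at day 7 the bound applied was not the one set before.

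A test of the difference between groups singled out these results. The In minus S effect differed between the sexes in 17 gene lists with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05 by camera), and 29 of 100 drawn splits gave as many as with the preset one (highest other 25), so chance cannot be excluded. For single genes this difference gave 0 by edgeR (619 at an unadjusted p under 0.05, 6 by DESeq2). Any split reaches a count of 0, so the 100 drawn splits (highest other 10) do not test it. The male effect differed between day 30 and day 7 in 1518 genes, in 21 gene lists (1 with an estimated correlation) and by a median of -2.76 (log2) for endothelial markers. Of 100 drawn splits 5, the real one included, gave as many genes (highest other 1895), but all 5 kept the day 7 groups as labelled, as 7 of the drawn splits did, and so still hold any day 7 difference, and this share does not tell whether chance can be excluded. Splits that did not keep them gave at most 0 genes.

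At day 7 4090 genes differed, with vascular and microglial genes such as Cldn5 higher in the inj libraries, which were also deeper, and with these libraries thinned to the Sham depth 3569 genes passed (87.3% of the count), which argues against depth as the whole cause. A lower share of neurons would raise the markers of every other cell type alike. The endothelial median lay above the oligodendrocyte median by 2.96, more than the larger interquartile range of 1.15. These lists had already been seen to part when the test was chosen, so that outcome was known in advance. More nuclear RNA in Sham would lower the nuclear-retained list. Its median was 0.38, and by the bound set before, a median of 0 or higher speaks against this cause. That median was smaller than the interquartile range of 0.59, however. Of the members 5 rose and 3 fell past the threshold, Pnisr the furthest (-2.74). The explanation is therefore left open, by a stricter bound than the one set before. A batch that held 1 group alone cannot be told apart from the groups, since the totals separate them, and a larger share of vessel cells and microglia, which enrichment for neurons would lower, and the injury itself stay open, untested. The 6 libraries make 10 splits, too few for a share under 0.05: as labelled they gave 4090 genes and the highest other split 0 (1 of 10 as large), and for lists 17 and 30 (7 of 10).

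Choroid plexus markers were higher in the female In libraries at day 30. Without In 3 their median was still 4.93, which argues against the library In 3 alone. Choroid plexus tissue in the female In libraries may be a source: a second choroid plexus list had a median of 1.86 with 11 of 11 tested members above 0, but this lies between the bounds of 0.5 and 2 set before, so the test leaves it open. Across the 9 tested markers the ratio of In 3 to In 1 had a median log2 of 3.17 (SD 0.69), and Slc13a4 and Aqp1 were also present in the S libraries (246 and 40 counts in S 1). Ttr, an abundant transcript of this tissue, is listed at 0 in all day 30 libraries, as are 404 genes of the day 7 table, so its level decides nothing, and a change in cortical cells after injury stays open, untested.

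Between the sexes at day 30, after TMM scaling, ribosomal and mitochondrially encoded genes were lower and vascular genes higher in females. Mitochondrially encoded genes that take more of the counts in males would move all other genes alike. The endothelial median lay above the ribosomal median by 1.49 in S and 1.61 in In, more than the larger interquartile ranges of 0.53 and 0.82. These lists had already been seen to part, so that outcome was known in advance. With mitochondrially encoded genes left out 419 genes differed in S and 1885 in In, against 447 and 1913. TMM scaling had already taken out a shift common to all genes, so these counts could hardly change and do not test this cause. The parting of the endothelial and ribosomal lists shows only that a shift common to all other genes does not account for both. More nuclear RNA in the female libraries is left open by the nuclear-retained list, with medians of 0.23 in S and 0.071 in In over members that went both ways. The mitochondrial share separated the sexes by 16.2 percentage points, as a library batch could, and since no label gives a batch, batch and sex cannot be told apart. Sex itself stays open, untested.

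For the comparisons below, 10 splits are too few for a share under 0.05. Female against male gave 447 genes in S and 1913 in In, with a highest other split of 0 in both (1 of 10 as large each). In females In against S gave 5 genes (highest other 1, 1 of 10 as large) and 10 lists (highest other 21, 8 of 10). In males it gave 0 genes by edgeR (1232 at an unadjusted p under 0.05, 2 by DESeq2), as did 10 of 10 splits, and 17 lists (highest other 17, 2 of 10).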

How the results depend on the processing

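The alternatives with library totals, thinned libraries, male In 1 and male S 2 left out together, mitochondrially encoded genes left out, a choroid plexus score as covariate and genes at 0 left out were chosen after the data were seen. The others were set before.

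At day 7 the count of 4090 genes stayed within 1.5 times under all alternatives run (2926 without inj 2 to 4968 with limma-voom). The time contrast (1518 genes) gave 2635 with limma-voom and, leaving out 1 library, between 1004 (inj 2) and 2028 (male In 1).

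In males at day 30 the count of 0 became 2 with DESeq2 and 1 without male In 1 and male S 2 together, and without 1 library lay between 0 (In 3) and 1 (In 1, and also In 2). In females the count of 5 became 33 with DESeq2, 10 with no filter (without Folr1), 10 with a replicate block (without Plvap), 4 with library totals (without Slco1a5), and 0 with limma-voom (633 at an unadjusted p under 0.05), with only the compared groups (446) or with the choroid plexus covariate (373), which takes up the signal itself. Leaving out 1 library gave between 0 (each but In 1) and 24 (In 1). The difference between sexes gave 6 with DESeq2 and 0 otherwise.

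Female against male in S (447 genes) gave 1038 with DESeq2, 953 with limma-voom, 21 with a replicate block, 946 with only these groups, 981 without male In 1 and male S 2, 8998 with library totals, and between 66 (female S 1) and 418 (male S 1) without 1 library, with 68 without male S 4, 116 without female S 2, 159 without male S 2 and 162 without female S 3. In the In libraries (1913) it gave 668 with only these groups, 8969 with library totals, and between 578 (female In 2) and 1908 (female In 1) without 1 library, with 821 without female In 3. Library totals turned Mapt (0.79) and Tardbp (0.79) in the In libraries and Sod1 (0.71) in S upwards, as that scale moves the median of all genes.

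With an estimated correlation 0 lists passed at day 7, in males and for the difference between sexes (7, 0 and 3 at an unadjusted p under 0.05 by camera), and 2 in females, with 1 in the time contrast. Without male In 1 and male S 2, 6 lists passed in males and 10 for the difference between sexes. Without 1 library the lists ran from 8 (In 1) to 20 (In 3) in males and from 11 (female In 2, male In 1 or male S 1) to 24 (male In 3) for the difference.

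For genes named in the report, 2526 combinations of gene and alternative kept direction and side of the threshold, 81 lost a call, 24 gained one and 60 turned direction. Of the last, 0 were calls as reported, and 3 passed once turned, those of Mapt, Tardbp and Sod1 above. Library totals also turned Apoe (0.0303) and Sod1 (0.37) between the sexes in In, Aif1 (0.50) and Mapt (0.18) in S, Aif1 (0.0103), Sod1 (0.19) and Tardbp (0.0555) at day 7, and Apoe (-0.20) and Mapt (-0.00964) in the time contrast. Limma-voom turned Gfap in females (-0.14), App in males (0.13), App (-0.10) and Gfap (-0.00479) for the difference, and Apoe in S (-0.00335) and in the time contrast (-0.25), where no filter (-0.0103) and the filter at 1 CPM (-0.00162) turned it too. The block turned Gfap in females (-0.0391), in males (0.14) and for the difference (-0.18). Its male side rests on male In 1, male In 2, male S 1 and male S 2. Leaving out male In 1 and male S 2 turned Aif1 (-0.0671) and App (0.13) in males and App for the difference (-0.11). The covariate turned Tardbp (0.45). Without 1 library, values that turned ran in females from -0.33 to 0.23 (Apoe), -0.0594 to 0.0743 (App), -0.35 to 0.22 (Gfap), -0.0378 to 0.14 (Mapt) and -0.18 to 0.0569 (Tardbp), in males from -0.29 to 0.16 (App), -0.51 to 0.0974 (Fos) and -0.14 to 0.0935 (Gfap), for the difference from -0.15 to 0.31 (App) and -0.32 to 0.23 (Gfap), between the sexes from -0.30 to 0.0612 (Mapt, In), -0.24 to 0.32 (Apoe, S), -0.22 to 0.0127 (Sod1, S) and -0.0201 to 0.0966 (Tardbp, S), and in the time contrast from -0.29 to 0.24 (Apoe).

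No paired analysis was possible at day 7 because the groups share only number 3. Except where stated, the cause was not tested. The Sham depth limits what can be seen in genes near its floor.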

Other observations

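The genes in this part were chosen after their values were seen. Among nuclear-retained genes at day 7, Son, a protein of nuclear speckles (-2.55, log2, adjusted p = 0.000385 by edgeR), Pnisr (-2.74, 7.89e-05) and Prpf38b, a splicing factor (-1.78, 0.00123), fell, while Ogt, which attaches sugars to nuclear proteins (0.76, 0.002), and the helicase gene Ddx5 (0.62, 0.00665) rose. Stra6, a receptor for retinol-binding protein, rose at day 7 (3.26, adjusted p = 0.000479) and was higher in females than males at day 30 in S (1.33, 0.00442) and In (1.48, 0.00137).

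Of 12397 genes in both tables, 404 were listed at 0 in all day 30 libraries. At day 7, 174 of these had over 10 CPM on average, among them Fth1, the heavy chain of ferritin (10121), the tubulin gene Tuba1b (666), Palm (510.2), Map1lc3b, a protein of autophagosomes (259), Myh11, the smooth muscle myosin (213), and the ribosomal protein gene Rpl8 (197). With these genes left out of the time contrast, 1523 genes passed.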
